A study of Mus musculus with 6 samples.

How the data were processed

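Per the labels' protocols, total RNA was extracted with TRIZOL from mouse embryonic fibroblasts grown from E13.5 embryos in medium with 10% fetal bovine serum, and 1 ug was taken into an Illumina TruSeq RNA kit. How RNA was selected beyond the kit's name is not given in the sources used here. There was 1 library for each of 6 genotypes, and the labels give no replicate numbers and no batches. The authors deposited 1 table of raw read counts per library, with a gene symbol and a count in each line and no scaling. The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.0.10, HTSeq and DESeq2 and the genome build mm9, but not their roles, the strand setting, the counting mode or the annotation. Each table held 25793 genes, of which 5828 had 0 counts in all 6 libraries, and 5 closing summary lines in the style of HTSeq. The summary lines were left out of library sizes and tests. Reads on no gene made up 32.6, 30.9, 30.9 and 31.5% of all records in the WT, Sptbn1 heterozygous, Sptbn1 homozygous and Smad3 heterozygous libraries, and 12.2 and 11.9% in the Smad3 homozygous and double heterozygous ones; reads placed at several sites made up 32.5 to 47.1%. Reads that fit several genes made up 0.025 to 0.827%, and the lines for low quality and unaligned reads held 0 in every library.

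Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3, and levels are counts-per-million (CPM) of the scaled size. For each of 9 pairs of libraries, the ratio of scaled counts was computed for 14824 genes with at least 1 CPM in at least 1 library, with an exact Clopper-Pearson 95% interval from scipy 1.17.1. A gene counts as higher or lower when the whole interval lies beyond 1.5-fold. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only; they compare libraries, not genotypes, and no p-value was computed for pairs. A count of 0 was replaced by the floor of 3 counts per library to give a lower bound of a fold. The departure of the double heterozygote was the log2 level minus those of the single heterozygotes plus that of WT, after adding 0.5 counts, and was counted when it exceeded 1.5-fold by more than its 95% counting error. A gene stood apart in a library when the interval of its ratio to the nearest of the other 5 libraries lay beyond 1.5-fold. A set of 40 gene lists was fixed from general knowledge, with 1060 of 1101 member genes found in the tables, some under older symbols. For each list the members higher and lower were counted, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

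The effect per mutant allele was fitted with edgeR's quasi-likelihood test (robust; limma 3.58.1) to the number of mutant alleles of each gene, over 14091 genes with at least 1 CPM in at least 2 libraries and with 3 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation of that fit was 0.467, against 0.112 in the 4 libraries with the lower share of reads on genes. The spread in this fit holds embryo differences, preparation differences and any departure from an equal effect per allele. Alternatives were DESeq2 size factors, total counts, no filter, a filter of 5 CPM, a threshold of 2-fold, intervals widened by the dispersion of the allele-dose fit, DESeq2 1.42.0 with a Wald test, carriers against non-carriers, the fit without the other gene, and the fit without each library in turn. Those added after the data were seen were intervals widened by the dispersion within the 4 libraries with the lower assigned share, those 4 libraries alone, the removal of 94 histone, small structural, ribosomal RNA, Malat1 and Neat1 genes, genes of middle length and GC content, and random lists matched on length and GC content.

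The pair rule was tested on simulated data with 200 of 14824 genes changed. Against WT it recovered 60 to 75% of 2-fold changes and 87 to 95.5% of 4-fold changes, with the lowest 2-fold share in the Sptbn1 homozygote and the highest in the Smad3 homozygote and double heterozygote, no wrong sign, and 2 to 8 calls among unchanged genes. For the departure it recovered 53% and 85.5%. These simulated counts held counting error only, with no difference between embryos or preparations. Calls that such differences would add among unchanged genes are therefore not covered. The allele-dose fit for Sptbn1 was tested on simulated data with 200 of 14091 genes changed: at the dispersion of all 6 libraries it recovered 0, 0.5 and 75% of genes changed 1.5-, 2- and 4-fold per allele, and at the dispersion of the 4 libraries 80, 96.5 and 99%.

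Genes named in the text follow a rule set before the data were examined, as were the comparisons, the gene lists and the first group of alternatives. The rule takes, for each mutant against WT, the 12 higher and 12 lower genes whose interval bound nearest to 1-fold is largest, without predicted gene models, 8 per side for the departure, 5 per side for genes standing apart, and up to 4 members per list and direction. The same number per side was taken for the other 4 pairs, a choice made after the data were seen. The reference annotation was of build GRCm38.p6 and the tables of mm9, so it gave only gene names, chromosomes, biotypes, transcript length, GC content and which genes overlap; no coordinates are printed. Length and GC content were found for 94.4% of the measured genes. Because the strand setting is not stated, reads of overlapping and antisense genes cannot be separated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.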

Results

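RNA from primary mouse embryonic fibroblasts of 6 genotypes was sequenced, with 1 library per genotype. The cells were grown from E13.5 embryos of parents heterozygous for a knockout of Sptbn1, which encodes the membrane-skeleton protein beta-II spectrin, or of Smad3, a transcription factor activated by TGF-beta receptors. The labels name wild type (WT), Sptbn1 heterozygous and homozygous, Smad3 heterozygous and homozygous, and double heterozygous cells. The counts on genes came to 11407587 in WT, 6888076 and 6856680 in the Sptbn1 heterozygote and homozygote, 10477425 and 21329087 in the Smad3 heterozygote and homozygote, and 31125055 in the double heterozygote. With 1 library per genotype there is no replicate check, so each comparison describes these libraries and not the genotypes. Ranges in parentheses after a fold are exact 95% intervals of the count ratio, which cover counting error only. Where a gene list is placed among 10000 random lists of the same size and expression, the percentile describes these libraries and is no test. A gene is called higher or lower when that whole interval lies beyond 1.5-fold, and 14824 genes with at least 1 CPM (counts-per-million) in at least 1 library were compared.

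The targeted genes were examined first. Sptbn1, listed in the files under its older symbol Spnb2 and located on chromosome 11, was at 75.5% (73.4 to 77.6) of its WT level in the library labelled Sptbn1 heterozygote and at 54.3% (52.6 to 56.1) in the one labelled Sptbn1 homozygote. It was also lower in the library labelled double heterozygote, at 48.9% (695 against 1419 CPM), and in the one labelled Smad3 homozygote, at 72.0% (70.6 to 73.5), and stood at 109.6% (107.2 to 112.1) in the Smad3 heterozygote. Smad3, on chromosome 9, ran against the labels: it was at 149% (133.9 to 165.8) of WT in the library labelled Smad3 heterozygote, at 199.3% (182.2 to 218.2) in the one labelled Smad3 homozygote and at 380.7% (350.2 to 414.6) in the one labelled double heterozygote. In the Sptbn1 heterozygote and homozygote, Smad3 was at 108.2% and 107.3%, with intervals that include the WT level. The labels do not say which part of either gene was removed, and counts over a whole gene need not show the loss of an exon. A mislabelled sample was neither tested nor excluded, so what each genotype name stands for is not certain from these counts. Genotype names are those of the labels throughout, so a direction per Smad3 allele is one per labelled allele, against which the Smad3 counts run.

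**Figure D1:**
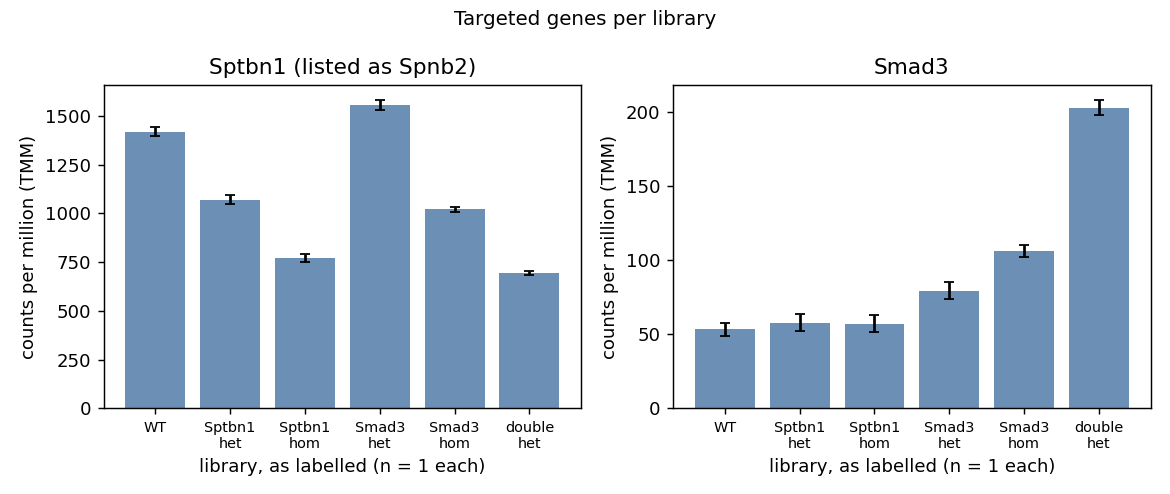
Level in CPM (counts-per-million, TMM-scaled, vertical axes) of the targeted genes Sptbn1 (left) and Smad3 (right) in each of the 6 libraries, 1 per genotype; bars start at 0 and error lines are exact 95% Poisson intervals of the count. Sptbn1 was lowest in the double heterozygote, at 695 CPM against 1419 in WT, and Smad3 was highest there, at 203 CPM against 53.3 in WT.

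Transcripts specific to one sex separated 1 library from the other 5. Xist, the RNA that coats the inactive X chromosome, was at 2747 CPM in the library labelled Smad3 heterozygote and at 16.3 CPM in WT, with lower values in the other 4 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were each at or below 0.388 CPM in the Smad3 heterozygote and at 35.0 CPM or more in every other library. The Smad3 heterozygote thus carried the transcripts of a female embryo and the other 5 those of males, so its comparisons with them also compare the sexes.

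The libraries labelled Smad3 homozygote and double heterozygote also differed from the other 4 in their make-up. Of the uniquely placed reads, 80.1% and 81.2% were assigned to genes in these libraries, against 40.9 to 43.3% in the other 4. The 18S ribosomal RNA Rn18s was the most abundant transcript in those 4, at 64661 to 87249 CPM, and was at 349 CPM in the Smad3 homozygote and 1529 CPM in the double heterozygote. The nuclear non-coding RNA Malat1 was at 38532 CPM in WT, 4473 in the Smad3 homozygote and 335 in the double heterozygote. The small non-coding RNAs Rn7sk and Rmrp, which act in transcription and RNA processing, were at 4153 and 2482 CPM in the Smad3 homozygote and at 0.605 and 0.255 CPM in the double heterozygote. The linker histone gene Hist1h1e was at 117 CPM in WT, 272 in the Smad3 homozygote and 0.0960 in the double heterozygote, and the nuclear RNA Neat1 at 338, 103 and 713 CPM, so the 2 libraries differed from WT in opposite directions for these. Across genes, which are not independent replicates, the correlation of log2 levels was 0.966 to 0.988 among the 4 libraries, 0.835 to 0.858 between them and the Smad3 homozygote, 0.876 to 0.887 between them and the double heterozygote, and 0.863 between those 2.

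**Figure D2:**
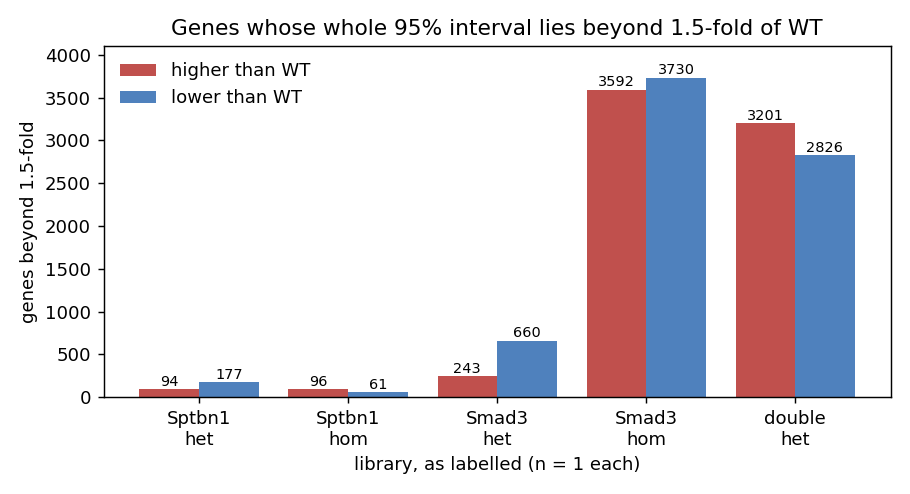
Number of genes (vertical axis) whose whole 95% interval lay beyond 1.5-fold of the WT library, higher (red) or lower (blue), for each of the 5 mutant libraries, 1 per genotype. The counts were 94 and 177 for the Sptbn1 heterozygote, 96 and 61 for the Sptbn1 homozygote, 243 and 660 for the Smad3 heterozygote, 3592 and 3730 for the Smad3 homozygote and 3201 and 2826 for the double heterozygote.

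The library labelled Sptbn1 heterozygote was compared with WT to ask what differs when 1 allele of beta-II spectrin is mutant. Secreted inflammatory factors were lower: 15 of 38 measured members were lower and 0 higher, with the interleukin genes Il1b and Il1a 12.9-fold (4.87 to 48.5) and 10.4-fold (3.87 to 39.1) lower and the chemokine gene Ccl2 2.39-fold lower. The list's median log2 ratio was -0.91, or -0.74 with members at 0 counts in 1 library placed at their bound of 3 counts. The list of matrix metalloproteinases, which cut extracellular matrix, with related proteases and inhibitors, followed. In it 7 of 30 were lower, among them Mmp10 (3.54-fold), Mmp3 (2.48-fold) and Mmp13 (2.20-fold). Of the interferon-stimulated genes, 6 of 46 were lower, including the RNA sensor gene Oas3 (4.41-fold, 3.24 to 6.15) and the antiviral gene Rsad2 (3.15-fold). Among the highest genes were Rspo1, a secreted amplifier of Wnt signalling, 9.17-fold (7.35 to 11.6) higher, the ubiquitin ligase gene Trim39 9.83-fold (9.12 to 10.6) higher, Plekhg5 4.37-fold (3.57 to 5.37) higher and Scube1 3.06-fold (2.48 to 3.78) higher.

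Markers of macrophages and leukocytes moved with the inflammatory genes in this library: 7 of 23 were lower, led by Fcgr1 (3.31-fold) and Cd52 (3.26-fold). The protease inhibitor genes Serpina3h and Ctla2a, the latter an inhibitor of cathepsins, were 41.6-fold (20.97 to 96.8) and 5.03-fold (4.49 to 5.67) lower, and Gata4, a transcription factor of heart and gonad, was 7.41-fold (3.25 to 20.8) lower. The 39 TGF-beta and SMAD3 target genes had 0 members higher and 0 lower, and a median log2 ratio of -0.12 at percentile 0.04. Of 45 TGF-beta pathway components, 1 was lower, the BMP antagonist Grem1 1.83-fold lower. In the imprinted cluster of distal chromosome 7 that holds Igf2 and H19, the median log2 ratio was 0.27 (percentile 99.98), and 1 of 12 genes was higher, the growth-restraining RNA H19 1.66-fold higher. Collagens and other matrix genes had a median of 0.01 with 2 of 53 higher, Ogn (2.04-fold) and Fbn2 (1.77-fold). Mitotic and DNA replication genes had no member higher or lower among 38 and 40. In all, 94 genes were higher and 177 lower; the count beyond 2-fold was 97, and with intervals widened by the between-library dispersion of the allele-dose fit it was 21. The guanylate-binding protein gene Gbp1 and the ribosomal protein gene Rpl30 also ranked among the highest, but they belong to gene families with near-identical copies whose reads cannot be placed with certainty.

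The library labelled Sptbn1 homozygote was compared with WT to ask the same of 2 mutant alleles. The matrix and bone genes Spp1 (osteopontin) and Mmp13 were 2.62-fold (2.49 to 2.76) and 2.37-fold (2.19 to 2.57) lower, and Nt5e, the cell-surface enzyme that makes adenosine, was 3.66-fold (2.96 to 4.57) lower. Col2a1, the main collagen of cartilage, was 9.96-fold (7.04 to 14.4) higher, and Trim39, Rspo1 and Plekhg5 were again higher, by 7.18-fold (6.64 to 7.77), 6.36-fold (5.05 to 8.07) and 3.24-fold (2.62 to 4.02). Few genes of the pathway lists were called: 3 of 30 metalloproteinases and their inhibitors were lower (median log2 ratio -0.13, percentile 0.01), and 2 of 38 inflammatory factors, the chemokine genes Cxcl10 (2.83-fold) and Cxcl5 (1.94-fold). None of 46 interferon-stimulated genes was called, with a median of -0.16 at percentile 0. TGF-beta and SMAD3 targets had 0 of 39 higher, 0 lower and a median log2 ratio of 0.00.

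Among TGF-beta pathway components, the activin antagonist Fst was 2.97-fold higher and Grem1 1.73-fold lower, out of 45. The smooth muscle contractile genes had a median log2 ratio of 0.13 (percentile 99.99) with no member beyond the rule, and the imprinted cluster around Igf2 and H19 one of 0.17 (percentile 99.78), also with none. Macrophage markers had a median of -0.32, with 2 of 23 lower, the lysozyme gene Lyz2 (1.68-fold) and the complement gene C1qb (1.83-fold). Hoxd13, a homeobox gene of the distal limb, was 9.28-fold (2.99 to 46.6) lower. In all, 96 genes were higher and 61 lower; the counts were 97 in total among genes with at least 5 CPM in some library, 47 beyond 2-fold and 12 with the widened intervals.

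Genes shared by both Sptbn1 libraries were counted next, since both are set against the same WT library. Of the genes higher in the heterozygote and in the homozygote, 32 were the same, and of those lower, 23. If the calls were independent, 0.61 and 0.73 would be shared, and counts simulated for a shared WT library without any difference gave means of 1.32 and 0.3 and highest values of 5 and 3. The simulation drew a deviation for each library from the common dispersion of the 4 libraries with the lower share of reads on genes, 1 value for all genes, so genes that vary more between embryos are not covered. The shared higher genes included Trim39, Rspo1, Plekhg5 and Ptn, a heparin-binding growth factor at 271 CPM in WT, 555 in the heterozygote and 494 in the homozygote. The shared lower genes included Mmp3, Mmp10, Mmp13, Spp1, Grem1 and Penk, the enkephalin precursor, at 28.9, 8.69 and 11.95 CPM. Against the Smad3 heterozygote, 27 of the 32 higher genes but 12 of the 23 lower ones were beyond 1.5-fold in the same direction in both. Xist is among these 12, since the Smad3 heterozygote library came from a female embryo. In that library Mmp3, Mmp13 and Penk were at 129.8, 44.0 and 2.81 CPM, so their lower level is not particular to the Sptbn1 libraries. Ptn and Penk were picked after their values were seen.

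Between the libraries labelled Sptbn1 homozygote and heterozygote, 137 genes were higher in the homozygote and 56 lower. Inflammatory factors accounted for part of this, with 11 of 38 higher, 0 lower and a median log2 ratio of 0.66 (0.49 with 0 counts at their bound), including Il1b (11.2-fold), Il1a (10.7-fold) and the acute-phase gene Saa3 (3.32-fold, 2.90 to 3.8). Serpina3h (26.8-fold, 13.3 to 62.8), Ctla2a (3.8-fold, 3.36 to 4.31) and Gata4 (8.12-fold, 3.47 to 23.2) were also higher in the homozygote. Macrophage markers were higher for 4 of 23 and mesothelium, kidney and gonad markers for 5 of 11. Alx1, a homeobox gene of the face, was 8.87-fold (3.18 to 34.3) lower, and Gsta4, a glutathione transferase, 3.13-fold (2.23 to 4.48) lower. The count was 63 beyond 2-fold and 13 with the widened intervals.

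The library labelled Smad3 heterozygote was compared with WT to ask what differs when 1 Smad3 allele is mutant. Extracellular matrix genes were lower: 21 of 53 were lower and 1 higher, led by elastin, Eln, 31.3-fold (24.6 to 40.6) lower, the microfibril gene Mfap4 6.53-fold lower and the fibrillar collagen Col3a1 2.96-fold lower. Markers of other cell types moved in the same library, with 4 of 12 epithelial markers higher and 7 of 16 neural and glial markers lower, so a different mix of cells is not separate from the matrix difference. Interferon-stimulated genes were lower for 17 of 46, among them Iigp1 (4.98-fold), Gbp3 (4.30-fold) and the regulator Irf7 (3.69-fold), and 0 were higher. TGF-beta and SMAD3 targets were lower for 7 of 39, with the collagen receptor Itga11 4.62-fold and Angptl4 6.58-fold lower, and higher for 3, with the chromatin gene Hmga2 3.28-fold higher. Higher outside the lists were the peptide hormone gene Cck (31.15-fold, 26.3 to 37.1), the chemokine-like gene Rarres2 (5.46-fold, 4.34 to 6.95) and the actin nucleator Fmn2 (6.79-fold, 4.85 to 9.74). Serpina3n, a protease inhibitor, was 11.8-fold (9.97 to 14.1) lower, the interferon-inducible Ifi202b 97.53-fold (44.6 to 267) and the sodium channel gene Scn7a 15.4-fold (9.72 to 26.0).

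Metalloproteinases and their inhibitors were lower for 10 of 30, including Mmp13 (6.32-fold) and Mmp9 (5.46-fold), and higher for 2. The IGF-binding protein genes Igfbp2, Igfbp3 and Igfbp5 were 4.21-fold, 3.45-fold and 3.17-fold lower, within 6 of 22 IGF signalling genes that were lower, with 1 higher. Against WT the same list had 8 higher and 5 lower in the double heterozygote, and 5 higher and 9 lower in the Smad3 homozygote. In the imprinted cluster, H19 and the growth factor Igf2 were 2.41-fold and 1.61-fold lower. Wnt pathway genes were lower for 8 and higher for 3 of 33, with the stem-cell receptor Lgr5 7.20-fold lower and the feedback gene Axin2 3.47-fold lower. The contractile genes Actg2 (2.60-fold), Cnn1 (2.56-fold) and Acta2 (1.65-fold) were higher. Cholesterol synthesis genes had a median log2 ratio of 0.47 and 3 of 33 higher. DNA replication and mitotic genes had medians of 0.38 and 0.25, both at percentile 100, with no member beyond the rule. In all, 243 genes were higher and 660 lower, and the comparison is also one of a female with a male library. The count was 434 beyond 2-fold and 97 with the widened intervals.

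**Figure D3:**
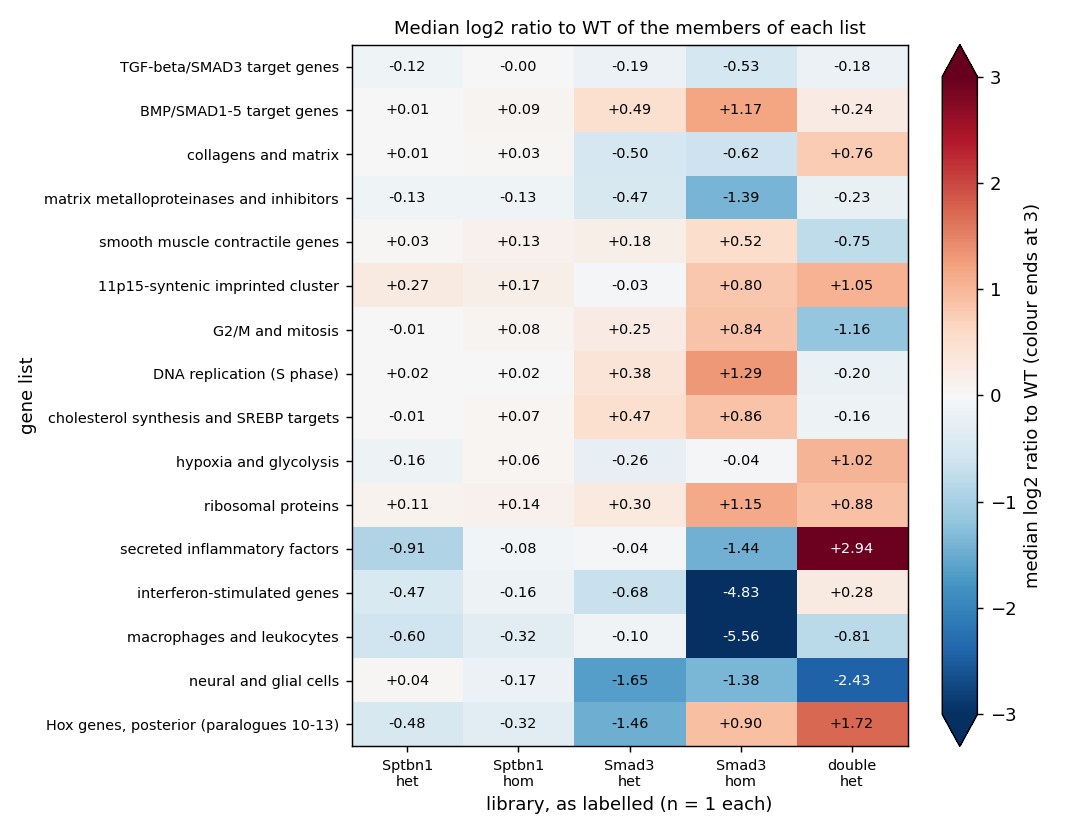
Median log2 ratio to WT (colour and printed value) of the measured members of 16 gene lists (rows) in the 5 mutant libraries (columns), 1 library per genotype; the colour scale ends at 3 in either direction. Inflammatory factors had a median of 2.94 in the double heterozygote, and interferon-stimulated genes one of -4.83 in the Smad3 homozygote.

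The library labelled Smad3 homozygote was compared with WT to ask what differs when both Smad3 alleles are mutant. Immune genes were far lower: 44 of 46 interferon-stimulated genes were lower and 0 higher, with the antiviral genes Oasl2 489-fold (248 to 1135) lower, Isg15 194-fold lower and Ifit1 100-fold lower. All 23 measured markers of macrophages and leukocytes were lower as well, including the lysozyme gene Lyz2 (39.6-fold), Itgam (72.4-fold) and C1qb (66.1-fold), and the list's median log2 ratio was -5.56, or -5.42 with members at 0 counts at their bound. Inflammatory factors were lower for 19 and higher for 3 of 38, with the chemokine gene Cxcl9, at 0 counts, at least 1084-fold lower and Saa3 336-fold (162 to 837) lower. Cell-cycle genes were higher: 31 of 40 DNA replication genes, such as Mcm5 (5.37-fold) and Ccne1 (5.22-fold), and 24 of 38 mitotic genes, such as Ccnb1 (20.8-fold) and Cdc20 (4.82-fold). This library is 1 of the 2 with over 80% of uniquely placed reads on genes, a difference not separate from genotype here. Against WT the double heterozygote had 32 of 38 mitotic genes lower and its interferon-stimulated genes were split. The 2 libraries also differed from each other in small non-coding RNA, with Rn7sk at 4153 CPM here and 0.605 in the double heterozygote. Their unlike movement therefore does not speak against a preparation difference.

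TGF-beta and SMAD3 targets were lower for 18 of 39, with Itga11 34.0-fold, the matrix protein Postn 10.1-fold and fibronectin, Fn1, 4.85-fold lower, and higher for 7, with the transcription factor gene Junb 5.48-fold higher. BMP target genes went the other way, with 8 of 14 higher, among them Msx1 (21.3-fold), Id1 (5.36-fold) and the inhibitory Smad6 (5.81-fold), and 2 lower. Pathway components were split, 11 higher and 14 lower of 45. Matrix genes were lower for 27 and higher for 9 of 53, with the proteoglycans Dcn, Bgn and Lum 23.6-fold, 6.83-fold and 7.19-fold lower. Metalloproteinases and their inhibitors were lower for 24 and higher for 2 of 30, led by Mmp9 342-fold (173 to 794) lower and Mmp13 89.4-fold lower. Contractile genes were higher for 9 and lower for 3 of 24, including Tagln 7.70-fold higher, and cholesterol synthesis genes for 21 of 33, including the farnesyl diphosphate synthase gene Fdps 4.85-fold higher. In the imprinted cluster, H19 was 5.06-fold higher and the antisense RNA Kcnq1ot1 26.1-fold lower. The 133 annotated antisense RNAs had a median log2 ratio of -2.24 in this library, against -4.71 for Kcnq1ot1. A lower level of that class is not separate from the lower Kcnq1ot1. Where Kcnq1ot1 lies within the spread of the class was not examined. Ribosomal protein genes were higher for 27 of 42 and nuclear genes of oxidative phosphorylation for 19 of 38, with Rplp0 4.36-fold higher and Uqcrc1 4.47-fold higher; several ribosomal protein genes have near-identical copies. In all, 3592 genes were higher and 3730 lower, 49.4% of those measured; the count was 4857 beyond 2-fold, and it was 1892 with the widened intervals, 376 higher and 1516 lower. With total counts 3964 were higher and 3491 lower, so which side holds more genes depends on the setting. The median log2 ratio of all genes was 0.10 with TMM scaling, 0.04 with DESeq2 size factors and 0.19 with total counts, so small shifts of a list are not separate from the scaling.

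Between the libraries labelled Smad3 homozygote and heterozygote, 3361 genes were higher in the homozygote and 3303 lower. Interferon-stimulated genes were lower in the homozygote for 43 of 46 and macrophage markers for 23 of 23, with the chemokine genes Ccl6 and Ccl3 619-fold (284 to 1689.7) and 473-fold (161 to 2298) lower. DNA replication genes were higher for 26 of 40, and BMP targets for 7 of 14. Matrix genes were split, 14 higher and 21 lower of 53, and TGF-beta and SMAD3 targets were higher for 6 and lower for 14 of 39. Xist was 8834-fold (4287 to 21973) lower in the homozygote. The pair differs in embryo sex and in the share of reads on genes besides Smad3 allele number, and the count was 4207 beyond 2-fold and 1601 with the widened intervals, 332 higher and 1269 lower; with DESeq2 size factors 3090 were higher and 3526 lower. The median log2 ratio of all genes was 0.12 with TMM, 0.05 with DESeq2 and 0.22 with total counts.

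The library labelled double heterozygote was compared with WT to ask what differs when 1 allele of each gene is mutant. Secreted inflammatory factors were far higher: 30 of 38 were higher and 2 lower, with the neutrophil chemokine gene Cxcl5 106-fold (96.4 to 116) higher, the iron-binding Lcn2 69.5-fold (53.4 to 92.3) higher, complement C3 46.7-fold (43.2 to 50.7) higher and the inducible nitric oxide synthase Nos2 119.5-fold (62.9 to 262) higher. The granulocyte growth factor gene Csf3, at 1 count in WT, was 428-fold (76.6 to 16907) higher. Genes outside the lists included the metalloreductase Steap4 132-fold (102 to 173) higher and the chitinase-like Chi3l1 61.1-fold (46.3 to 82.4) higher. Mitotic genes were lower for 32 of 38, among them Mki67 (4.85-fold), Cenpf (8.19-fold) and Kif11 (3.97-fold), and 0 were higher. Collagens and matrix genes were higher for 29 of 53, with the collagen Col5a3 13.9-fold and Lum 7.41-fold higher, and lower for 10.

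Hypoxia and glycolysis genes were higher for 17 of 29, with the vasodilator peptide gene Adm 20.03-fold higher and Pdk1 3.24-fold higher. Targets of p53 and senescence genes were higher for 12 and lower for 3 of 29, including the cell-cycle inhibitor gene Cdkn2a (35.3-fold) and the death receptor gene Fas (9.35-fold). Smooth muscle contractile genes were lower for 12 of 24 and higher for 0, with Tpm1 2.73-fold lower and Myl9 2.74-fold lower. TGF-beta and SMAD3 targets were split, 8 higher and 16 lower of 39, with Angptl4 24.4-fold higher and Ctgf 4.98-fold lower. In the imprinted cluster, 7 of 12 genes were higher and 2 lower, the higher ones including H19 (3.77-fold), Cdkn1c (2.82-fold) and Igf2 (2.37-fold), and Kcnq1ot1 was 92.7-fold (78.3 to 110.3) lower. The 133 annotated antisense RNAs had a median log2 ratio of -1.27 in this library, against -6.53 for Kcnq1ot1. A lower level of that class is not separate from the lower Kcnq1ot1. Where Kcnq1ot1 lies within the spread of the class was not examined. Interferon-stimulated genes were split, 14 higher and 9 lower of 46, and macrophage markers were lower for 13 and higher for 3 of 23. Among the lowest genes were Hist1h1e 1222-fold (417 to 5934) lower and Malat1 115-fold (113 to 117) lower. This library is the other with over 80% of uniquely placed reads on genes, a difference not separate from genotype here. Matrix, mitotic and contractile genes had medians of 0.76, -1.16 and -0.75 log2 here and -0.62, 0.84 and 0.52 in the Smad3 homozygote. The 2 libraries also differed from each other in small non-coding RNA, so these opposite medians do not speak against a preparation difference. In all, 3201 genes were higher and 2826 lower, 40.7% of those measured; the count was 3473 beyond 2-fold and 1079 with the widened intervals, 350 higher and 729 lower; with DESeq2 size factors 2854 were higher and 3113 lower. The median log2 ratio of all genes was 0.09 with TMM, 0.00 with DESeq2 and 0.12 with total counts.

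**Figure D4:**
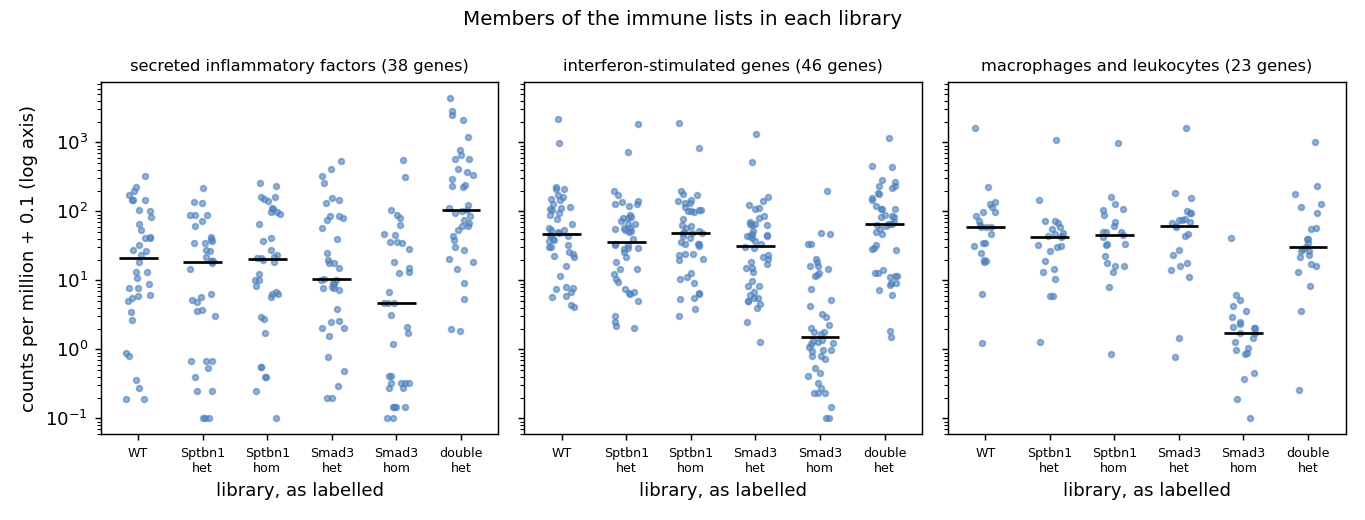
Level in CPM with 0.1 added (vertical log axis) of each measured member of 3 gene lists in the 6 libraries, 1 library per genotype; points are genes and the black line is the median gene. The inflammatory factors sat highest in the double heterozygote, where 30 of 38 were above WT by the size rule, and the interferon-stimulated genes and macrophage markers sat lowest in the Smad3 homozygote.

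The double heterozygote was set against each single heterozygote to ask what differs when an allele of the other gene is mutant as well. Against the Sptbn1 heterozygote, 34 of 38 inflammatory factors were higher, with Cxcl5 248-fold (207 to 299.7) higher and C3 74.1-fold (65.1 to 84.6) higher, and 31 of 38 mitotic genes were lower. Against the Smad3 heterozygote, 31 of 38 inflammatory factors and 38 of 53 matrix genes were higher (4 matrix genes were lower), with Steap4 179-fold (131 to 251) higher and complement factor B, Cfb, 64.4-fold (54.7 to 76.4) higher. Mitotic genes were lower in that comparison for 36 of 38 and contractile genes for 16 of 24. In all, 3130 genes were higher and 2705 lower than in the Sptbn1 heterozygote, and 3337 and 2808 than in the Smad3 heterozygote. The counts were 3398 and 3613 beyond 2-fold and 1156 and 1114 with the widened intervals, 398 higher and 758 lower in the first and 491 and 623 in the second; with DESeq2 size factors they were 2799 and 2983, and 2961 and 3172. The single heterozygotes had 41.7 and 43.3% of uniquely placed reads on genes, and against the Smad3 heterozygote the median log2 ratio of all genes was 0.10 with TMM, 0.01 with DESeq2 and 0.14 with total counts.

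The level of each gene in the double heterozygote was also set against the sum of the log2 differences of the single heterozygotes. Among the genes above that sum were Angptl4, a lipoprotein lipase inhibitor, by 7.97 on the log2 scale, Steap4 by 8.04, the limb gene Hoxd13 by 9.10 and Cxcl5 by 6.89. Hoxd13 rests on few counts (SE 0.98), at 0.88 and 0.29 CPM in the Sptbn1 and Smad3 heterozygotes. Below that sum were Cck, with a departure of -8.04, and the linker histone gene Hist1h1e, with -10.21 (SE 0.78, from 3 counts in the double heterozygote). The Cck value rests in large part on the Smad3 heterozygote, at 388.5 CPM. Cck was at 12.47 CPM in WT, 8.69 in the Sptbn1 heterozygote and 1.02 in the double heterozygote. Ddx3y (8.30) and Xist (-12.49) were also among the genes named by the rule, since 1 of the 4 libraries came from a female embryo. In all, 2746 genes lay above and 2442 below by more than 1.5-fold beyond the counting error; 3061 in total did so beyond 2-fold. With DESeq2 size factors 2452 lay above and 2751 below, and with the error widened by the between-library dispersion 259 and 439, 698 in total, so which side holds more genes depends on the setting. The double heterozygote had 81.2% of uniquely placed reads on genes and the other 3 libraries 41.7 to 43.3%, so that difference enters every departure.

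Each library was also set in turn against all 5 others, since every mutant is compared with the same WT library. The number of genes above or below all others was 5 for WT, 16 for the Sptbn1 heterozygote, 9 for the Sptbn1 homozygote, 113 for the Smad3 heterozygote, 2855 for the Smad3 homozygote and 1715 for the double heterozygote. In WT one of these was the cysteine dioxygenase gene Cdo1, at 187 CPM against 113 in the next library. In the Sptbn1 heterozygote Oxtr, the oxytocin receptor, was highest at 37.4 CPM and the cyclooxygenase gene Ptgs2 lowest at 87.2 CPM. In the Sptbn1 homozygote Aqp4, a water channel, was highest at 38.7 CPM, and in the Smad3 heterozygote Cck, at 389 CPM. Isg15 was lowest in the Smad3 homozygote, at 0.844 CPM, and Ccl20 highest in the double heterozygote, at 74.3 CPM. Among the 4 libraries with the lower share of reads on genes alone, a grouping chosen after seeing the data, the counts were 14, 54, 15 and 513 for WT and the Sptbn1 heterozygote, Sptbn1 homozygote and Smad3 heterozygote.

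A change per mutant allele was fitted over all 6 libraries, the one analysis with a test, which treats each further allele as adding the same log2 change. No gene passed for Sptbn1 allele number with edgeR (Benjamini-Hochberg adjusted p under 0.05), 23 of 14091 had an unadjusted p under 0.05, and DESeq2 called 0. No gene passed for Smad3 allele number with edgeR, 3311 had an unadjusted p under 0.05, and DESeq2 called 2048, of which 879 were higher and 1169 lower. The neural crest receptor gene Ngfr had a log2 change of -2.48 per Smad3 allele, the glial regulator Sox10 one of -2.80, the Wnt antagonist Sfrp4 one of -3.18 and the receptor tyrosine kinase gene Epha2 one of 1.81, each with an adjusted p of 0.174 in edgeR's quasi-likelihood test; these 4 and the genes named from lists in this paragraph were chosen after their values were seen. Adjusted over the list alone, edgeR called 8 of 14 BMP targets, with Smad6 at 1.26 and Runx2 at -2.04 per allele, 6 of 39 TGF-beta and SMAD3 targets, with Itga11 at -2.37 and Il11 at 2.98, 7 of 14 neural and glial markers and 4 of 12 genes of the imprinted cluster. At least 1 gene was called in 16 of the 39 lists, 23.5% of all genes tested had an unadjusted p under 0.05, and 2 of the 3 libraries labelled with mutant Smad3 alleles are those with over 80% of reads on genes, so these calls do not single out the lists named. No list had a call for Sptbn1 allele number when adjusted over the list alone. With each library left out in turn the counts of genes passing for Sptbn1 and for Smad3 stayed at 0. The Sptbn1 fit had little power. On simulated data at the dispersion of all 6 libraries it recovered 0, 0.5 and 75% of genes changed 1.5-, 2- and 4-fold per allele. The counts of 0 for Sptbn1 therefore do not show that its allele number has no effect. For Smad3 the number at an unadjusted p under 0.05 was 1976, 1470, 2625 and 899 without WT, the Sptbn1 heterozygote, the Sptbn1 homozygote or the Smad3 homozygote. It rose to 3843 and 4379 without the Smad3 heterozygote or the double heterozygote. For Sptbn1 it was 78, 4, 294 and 37 without WT, the Sptbn1 heterozygote, the Sptbn1 homozygote or the double heterozygote, and 21 and 26 without the Smad3 heterozygote or homozygote. Within the 4 libraries with the lower share of reads on genes, with 1 residual degree of freedom, edgeR called 339 genes for Smad3, 97 higher and 242 lower, from 1 heterozygous library that also differs in sex.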

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

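All tests weighed in this part were chosen after the results they bear on were seen, and for 1 of them, on strand-required counting, the bound that counts against the explanation was also reworded after its value was seen.

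For 4 of the 16 genes named for their departure, the difference that goes with the mutant Sptbn1 allele ran one way in the Sptbn1 heterozygote against WT and the other way in the double heterozygote against the Smad3 heterozygote, each beyond the size rule. The distal limb gene Hoxd13 had a departure of 9.098, the chemokine genes Cxcl5 and Cxcl2 6.894 and 8.902, and the guanylate-binding Gbp1 -14.783, all on the log2 scale. Gbp1 had 0 counts in the double heterozygote, so its value rests on the 0.5 counts added, and its reads cannot be told from those of near-identical family members with certainty. Its value rests on a low WT level as well, 0.265 CPM from 3 counts. Gbp1 was at 13.4, 16.1 and 10.3 CPM in the Sptbn1 heterozygote, Sptbn1 homozygote and Smad3 heterozygote. Gbp1 was also at 0.0 CPM in the Smad3 homozygote, the other library with the higher share of reads on genes. Cxcl2 was at 0.147 CPM in the Sptbn1 heterozygote, from 1 count. Hoxd13 was at 0.88 CPM in the Sptbn1 heterozygote and 0.29 CPM in the Smad3 heterozygote. The difference between the libraries was not tested for these genes, since each genotype has 1 library. The double heterozygote and Smad3 heterozygote also differ in the share of uniquely placed reads on genes, 81.2 against 43.3%, and in embryo sex. These opposite directions therefore cannot be assigned to the Sptbn1 allele, and the genes were named for their large departures.

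Of all records in a table, reads on genes included, the share that fits several genes was 0.413% in the Smad3 heterozygote and 0.827% in the double heterozygote, above the 0.395% of the WT library, and 0.366%, 0.363% and 0.025% in the Sptbn1 heterozygote, Sptbn1 homozygote and Smad3 homozygote; the 2 libraries with over 80% of reads on genes lie at opposite ends. The share placed at several sites was 46.442%, 47.09% and 43.814% in the Sptbn1 heterozygote, Sptbn1 homozygote and Smad3 heterozygote, above 42.895% in WT, and 38.852% and 32.528% in the Smad3 homozygote and double heterozygote, below it. Rn18s, a gene with many copies, was also more abundant in these 3 libraries than in WT, at 75405, 87249 and 75183 CPM against 64661. No explanation of these shares was tested.

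The first pattern weighed is the 7322 and 6027 genes beyond the size rule against WT in the libraries labelled Smad3 homozygote and double heterozygote. Transcript length or GC bias as the whole cause is argued against: among genes of middle length and GC content the share beyond the rule was 47.72% and 33.55%, against 49.39% and 40.66% of all genes. Counting that required one strand in the other 4 libraries would lower genes that overlap another on the opposite strand, and these were instead higher than others by 0.171 (-0.003 to 0.274) and 0.086 (0.013 to 0.148) log2; the explanation stays open because the first interval includes 0, but the bound as first worded, an upper end above 0, would have counted against it, while the lower medians of 133 antisense RNAs in these libraries (-2.24 and -1.27) go with it. The share of uniquely placed reads on genes was 80.09% and 81.18% in these libraries alone. Rn18s was at 349 and 1529 CPM in them, against 64661 in WT. The RNA make-up as counted thus differed from that of the other 4 libraries. How many of the 7322 and 6027 genes follow from RNA selection or counting cannot be told apart from genotype, since no genotype was prepared both ways. An effect of genotype also stays open and was not tested.

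The second pattern is the lower level of macrophage markers and interferon-stimulated genes in the library labelled Smad3 homozygote, lists that share 0 genes. Fewer macrophages in that culture stay open for the markers: that 23 of 23 were lower restates the pattern and is no test of it; the abundant Lyz2 and Mpeg1 were at 41.2 and 4.09 CPM against 1631 and 226 in WT. Whether this also covers the interferon-stimulated genes stays open, as their median log2 ratio was above that of the markers by 0.728 (-0.385 to 2.069). Transcript length or GC bias is argued against, because the interferon list lay at percentile 0.0 of random lists matched on expression, length and GC content. RNA preparation and the mutant Smad3 alleles stay open and were not tested for this pattern. The high share of reads on genes is shared with the double heterozygote, where interferon-stimulated genes were split (14 higher, 9 lower). The small non-coding RNA Rn7sk was at 4153 CPM in the Smad3 homozygote and 0.605 in the double heterozygote, so that split does not decide on preparation. In addition, 2 other libraries are labelled with a mutant Smad3 allele.

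The third pattern is the higher level of secreted inflammatory factors in the library labelled double heterozygote. More macrophages in that culture would go with higher macrophage markers, but these had a median log2 ratio of -0.815 and 13 of 23 were lower. The share of uniquely placed reads on genes was 81.18% there and 42.29% in WT. Of all measured genes, 40.66% were beyond the rule. The markers therefore give no sign of more macrophages, but cannot decide on their number across libraries of such different make-up. Length or GC bias is argued against by the list's percentile of 100 among lists matched on expression, length and GC content. The mutant alleles, the state of the culture and RNA preparation stay open as explanations that may apply, and none was tested for this pattern.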

How the results depend on the processing

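All results rest on 1 library per genotype, with depth limiting the genes of few counts. No list median whose 95% interval over members excluded 0 changed sign against WT; 11 did whose interval spans 0, among them mesothelium, kidney and gonad markers at 5 CPM, from -0.50 to 0.46 in the Smad3 heterozygote. Which side held more genes did turn: with DESeq2 size factors the departure had 2452 above and 2751 below against 2746 and 2442, and the double heterozygote 2854 higher than WT and 3113 lower against 3201 and 2826; with total counts the Smad3 homozygote had 3964 and 3491 against 3592 and 3730. Under the alternatives, 379 list medians, 193 values of named genes and 50 pair counts stayed within their limits, and 1, 3 and 22 did not. The limit was the 95% interval from resampling the members for a list median, the exact 95% interval of the count ratio for a named or targeted gene and 1.5 times for a count; the first is wide where members go both ways, so the 11 sign changes are among the 379. For counts of genes standing apart 11 stayed and 11 did not, for the departure 2 and 2, for the allele-number fits 21 and 3, and for the targeted genes 17 and 3. Counting beyond 2-fold gave 97, 47, 434, 4857 and 3473 genes against WT in the Sptbn1 heterozygote, Sptbn1 homozygote, Smad3 heterozygote, Smad3 homozygote and double heterozygote. It gave 63 and 4207 for homozygote against heterozygote of Sptbn1 and of Smad3, 3398 and 3613 for the double heterozygote against the single Sptbn1 and Smad3 ones, and 3061 for the departure. For genes standing apart it gave 0 in WT and 2, 3, 47, 1527 and 807 in the mutants in the order above. Intervals widened by the dispersion of the allele-dose fit gave, in the same order of pairs, 21, 12, 97, 1892 and 1079, then 13 and 1601, then 1156 and 1114, and 698 for the departure. Both settings are stricter by construction. With the dispersion within the 4 libraries of lower assigned share, chosen after seeing the data, the Sptbn1 heterozygote had 153 genes, the Sptbn1 homozygote 97, and the pair of them 106. At 5 CPM or more the Sptbn1 homozygote had 97 genes against WT and 5 standing apart, with fewer genes measured. Within those 4 libraries alone, 14, 54, 15 and 513 genes stood apart in WT, the Sptbn1 heterozygote, the Sptbn1 homozygote and the Smad3 heterozygote, where fewer libraries have to be exceeded.

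For Smad3 allele number, edgeR called 0 genes over all 6 libraries, 345 without Sptbn1 allele number in the fit and 339 within the 4 libraries, and DESeq2's Wald test called 2048; 3311 had an unadjusted p under 0.05 in the first of these, and the cause was not tested. Leaving out each library in turn gave 0 to 0 calls for Smad3 and 0 to 0 for Sptbn1. For Sptbn1 the fit to all 6 libraries recovered 0.5% of simulated 2-fold changes per allele, so this stability is no evidence of a missing effect. The level of Sptbn1 in the Smad3 homozygote was 69.0% of WT with DESeq2 size factors and 76.7% with total counts, and in the double heterozygote 46.1% with DESeq2 size factors, as the scaling of these libraries differs. The median log2 ratio of skeletal muscle markers in the Smad3 heterozygote was 1.716 at 5 CPM or more, where fewer markers were measured, against 0.13. No paired analysis was possible because there is 1 library per genotype and the labels give no replicate numbers.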

Other observations

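The test of X-linked genes in this part was chosen before its result was seen and all others after; the bound for the chromosome of Sptbn1 was reworded, with the same outcome, after its value was seen, and the test on the shared WT library was split by direction and given a new bound after its values were seen.

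Genes that mark body region and other cell types differed between the libraries. In the Smad3 homozygote and double heterozygote, 49.39% and 40.66% of all measured genes were beyond the rule, so counts there alone do not set a list apart. Posterior Hox genes, which pattern the distal limb and tail, were higher in the double heterozygote for 6 of 8 and in the Smad3 homozygote for 4 (1 was lower), while anterior Hox genes were lower for 4 and 6 of 13, with 1 higher in the latter. In the Sptbn1 heterozygote, Sptbn1 homozygote and Smad3 heterozygote the posterior medians were -0.48, -0.32 and -1.46 log2, or -0.16, -0.15 and -0.49 with members at 0 counts at their bound, and 1 member was lower in each. Middle Hox genes were lower for 5 of 12 in the Smad3 homozygote and 4 in the double heterozygote, where 1 was higher. Limb, trunk and face patterning genes were split in the double heterozygote, 9 higher and 8 lower of 38, and in the Smad3 homozygote, 7 higher and 9 lower; in the Sptbn1 homozygote their median was 0.24 at percentile 99.99 with no member beyond the rule. Skeletal muscle genes were higher in the Smad3 homozygote for 9 and lower for 1 of 16, with the actin gene Acta1 12.4-fold higher; in the Smad3 heterozygote 1 was higher, Acta1 by 16.6-fold (11.6 to 24.5).

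Neural and glial markers were lower for 7, 7 and 11 of 16 in the Smad3 heterozygote, Smad3 homozygote and double heterozygote, and for 0 and 0 in the Sptbn1 libraries; 3 were higher in the Smad3 homozygote. Epithelial markers were higher in the Smad3 heterozygote for 4 of 12, with the keratin gene Krt5, at 3 counts in WT, 25.9-fold (8.52 to 129) higher, and in the Smad3 homozygote for 6, with 1 lower. Mesothelium, kidney and gonad markers were lower in the Sptbn1 heterozygote for 5 of 11, and split in the Smad3 heterozygote, 4 higher and 3 lower, in the Smad3 homozygote, 3 and 3, and in the double heterozygote, 4 and 2. Chondrocyte and osteoblast markers were split in the Smad3 homozygote, 5 higher and 3 lower of 18, and in the double heterozygote, 6 and 6. Endothelial markers were lower for 2 and 3 of 9 in the Smad3 heterozygote and homozygote, and split in the double heterozygote, 3 higher and 2 lower. Adipocyte markers were lower for 3 and higher for 1 of 9 and hepatocyte and gut markers higher for 3 of 5 in the Smad3 homozygote. Erythroid markers had fewer than 3 measured members and were not summarised.

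Genes of DNA repair by the Fanconi pathway and homologous recombination were higher in the Smad3 homozygote for 12 of 27 (1 was lower) and lower in the double heterozygote for 6. CTCF and cohesin genes were lower in the double heterozygote for 7 and higher for 1 of 16, and spectrin and ankyrin genes were lower for 6 and higher for 2 of 19, against 5 and 2 in the Smad3 homozygote. The spectrin and ankyrin list lay at percentile 22.26 of random lists in the double heterozygote and 70.79 in the Smad3 homozygote. Of all measured genes, 40.66% and 49.39% were beyond the rule there, so such counts alone do not set a list apart. Telomerase and pluripotency genes were split in the Smad3 homozygote, 5 higher and 5 lower of 19, and in the double heterozygote, 2 and 5. Imprinted genes outside distal chromosome 7 were higher for 2 of 41 in the Sptbn1 heterozygote and 2 in the homozygote, and split in the Smad3 homozygote (12 higher, 11 lower) and double heterozygote (7 and 9). Immediate-early genes were split in the Smad3 homozygote, 8 higher and 5 lower of 25, and in the double heterozygote, 7 and 2, as were genes of the unfolded protein response, 8 and 4, and 6 and 4, of 29. Annotated antisense RNAs, 133 genes, had median log2 ratios to WT of -2.24 in the Smad3 homozygote and -1.27 in the double heterozygote, and 105 long intergenic RNAs -1.14 and -0.64, against 0.13 and 0.12 for protein-coding genes.

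Other assignments of the 6 labels to the libraries were fitted for allele number, 100 in all with the real one. A first draw was replaced because it held mirror images. For the Smad3 count at an unadjusted p under 0.05 both draws led to the same outcome. Assignments that exchange the roles of WT and the homozygotes were all treated as mirror images. Some of these test a different allele effect, so the draw left out some assignments close to the real one. At the adjusted threshold, 100 of 100 assignments gave as many genes as the real one for Sptbn1 and 100 of 100 for Smad3, as every assignment, with a highest other value of 0, gave 0 genes; a count of 0 is matched by any assignment, so this says nothing about chance. For the 3311 genes at an unadjusted p under 0.05 for Smad3, 3 of 100 assignments gave as many, with a highest other value of 3416 and a median of 274, which argues against chance alone within this draw. One of the others only exchanges the labels of the WT library and the Sptbn1 homozygote, and the other places the Smad3 homozygote and double heterozygote among those with no mutant Smad3 allele. Both set the libraries with over 80% of uniquely placed reads on genes apart from most of the others, so this count may follow that technical difference as well as Smad3. For Sptbn1, 82 of 100 assignments gave at least the real 23 genes and the highest gave 3305, which points to a structure of the libraries other than Sptbn1 allele number.

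A higher dose of X-linked genes in the female Smad3 heterozygote library is argued against: 489 X-linked genes differed from autosomal ones by a median of -0.035 (-0.075 to 0.009) log2. The 55 genes called in the same direction in both Sptbn1 libraries could reflect strain sequence carried along with the mutant allele, but of 52 with a known chromosome 3, or 5.77% (1.21 to 15.95), lay on chromosome 11 with Sptbn1, against 8.16% of measured genes. Strain differences not linked to Sptbn1 would not gather on that chromosome and were not tested. Chance values of the shared WT library as the whole cause are argued against for the higher genes, of which 27 of 32, or 84.4% (67.2 to 94.7), were beyond 1.5-fold in the same direction against the Smad3 heterozygote library too. For the lower genes, 12 of 23, or 52.2% (30.6 to 73.2), they stay open, because that interval holds both a majority and a minority. Xist is among these 12, and its outcome was fixed by the female Smad3 heterozygote library. The intervals for the higher and the lower genes treat genes as independent, though all were read from the same libraries. They therefore do not cover chance differences between libraries. The first bound, at least as many of all 55 holding as not, would have counted against chance for both, with 39 holding. Part of the excess of higher genes may still come from the shared WT library, which cannot be split.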
